A study of Mus musculus with 4 samples.

How the data were processed

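Total RNA from mouse liver was pooled in equal amounts from 5 animals per group and hybridised, 1 pool per array, to 4 one-colour (Cy3) Agilent mouse gene expression arrays on 1 slide, per the labels' protocols and the series' design text. The deposited intensity values were made with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes, which subtracted the background and detrended each array without scaling arrays to one another, per the file headers. The deposited flags for outlier, saturated and well-above-background spots have other values, 0 or 1, per the file headers. The authors' value table holds the same intensity divided by each array's 75th percentile: its ratio to that quotient was 1 for every array at the precision compared, which settles its scale, centring and direction. Its column medians were 0.0878 and 0.0896 for WT and KO at 3 weeks and 0.0853 and 0.0864 at 6 weeks. Probe positions are those of mouse build mm9, as the files give them.

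From there, the log2 of the processed intensity was taken and the log2 of the array's 75th percentile over non-control spots was subtracted. No spot was saturated, and 189, 196, 209 and 252 outlier spots were left out on the WT and KO arrays at 3 weeks and the WT and KO arrays at 6 weeks. Spots of one probe were averaged. Of 39429 probes, 27591 were named through their accession, 3493 through their symbol and 393 through a synonym in a RefSeq gene table, and 7952 kept the name in the file. Where a gene had several probes, the brightest on average was used, and 174 probes without a value on every array were left out. For 96 of 30026 genes the brightest probe was not well above background on some array where another probe was. Among 4489 genes with a second probe well above background on all arrays, 50 were past 2-fold on the brightest at 3 weeks and 40 of these had the same sign on the second probe, 21 of them past 2-fold too. At 6 weeks these numbers were 220, 187 and 90.

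A gene entered a comparison where it was well above background on at least 1 of the 2 arrays. Where only 1 of them was, the ratio is a bound against the higher of the dim array's lowest signal among probes well above background and the gene's own signal there. Differences between ages used genes well above background on all 4 arrays. With 1 array per group there is no test of a single comparison, and genes were counted at 2-fold, or 4-fold for the difference between ages. limma 3.58.1 in R 4.3.3 fitted age and genotype over the 4 arrays, with the spread taken from the difference between the ages. Medians of 36 gene lists were set against 10000 random lists of the same size drawn from the same deciles of mean signal. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

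The comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took Pnpla7 and all members of the choline, methionine and growth hormone lists. It also took the 12 highest and 12 lowest genes by the smaller of their ratios at the 2 ages, and per age the 5 highest and 5 lowest that lay within 1.5-fold at the other. The 8 highest and 8 lowest between ages in WT, the 5 highest and 5 lowest differences between ages, and up to 4 members of every other list by the smaller of their ratios followed. Apart from that of list members, these rankings took only genes well above background on the arrays they use, and left out clones and gene models without a symbol. Some genes the rule takes are not reported here. Genes named outside the rule were chosen after their values were seen.

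The steps were tested on simulated data made from 18870 real genes, all well above background on all 4 arrays, with noise drawn from the observed difference between ages. That noise was shuffled across genes, so it did not follow signal, and no dim gene or bound was included. The number of unchanged genes counted therefore does not carry over to the counts in the data, which include dim genes. Of 50 genes per fold size changed at both ages, counting at 2-fold at both ages found 22% at 2-fold, 84% at 3-fold, 92% at 4-fold and 100% at 8-fold, with 13 unchanged genes counted. limma found 0%, 0%, 2% and 78% of them. In the list test at 3 weeks, 2% of 100 unshifted lists of 15 genes stood apart, and 95% of lists shifted by 0.2 on the log2 scale.

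Alternatives were normexp background correction with an offset of 50 and quantile normalization, quantile normalization alone, median scaling, a filter on all 4 arrays, no filter, the mean of all probes, outlier spots kept, the authors' value table, thresholds of 1.5-fold and 3-fold (2.25-fold and 9-fold for the difference between ages), limma without the age term or with a trend in the variance prior, and random lists not matched on signal. The number of arrays limits the precision of every value.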

Results

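Gene expression was measured in the liver of C57BL/6N mice labelled as Pnpla7 knockout (KO) or wild type (WT) at 3 and 6 weeks of age. PNPLA7 is a lysophospholipase that acts on lysophosphatidylcholine, and the title of the series places it in the breakdown of phosphatidylcholine that feeds choline and methyl groups into the methionine cycle. Each of the 4 groups had 1 one-colour array, hybridised with RNA pooled from 5 livers. Of 43020 non-control spots per array, 28714 were well above background on the WT array at 3 weeks, 30697 on the KO array at 3 weeks, 29466 on the WT array at 6 weeks and 29203 on the KO array at 6 weeks. With 1 array per group no difference below has a replicate check, and genes are named by the size of their ratio. Rankings across all genes cover those with a symbol that were well above background on all arrays the ranking uses, so genes with only a bound can exceed them. The median spread between spots of one probe gave a log2 ratio an SD of 0.0988 at 3 weeks and 0.128 at 6 weeks, which leaves out differences between pools. It was taken from probes with 10 spots, all well above background, so it does not cover dim genes. The 95th percentile of the log2 SD between spots ran from 0.329 on the WT array at 3 weeks to 0.406 on the KO array at 3 weeks. All 4 arrays lay on 1 slide, so array position and group cannot be told apart.

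Pnpla7 itself was read by 1 probe, at chromosome 2, positions 24908961 to 24909192 of mouse build mm9. Its signal, in units of the array's 75th percentile, was 7.54 in WT and 6.70 in the array labelled KO at 3 weeks, a log2 ratio of -0.17. At 6 weeks it was 9.65 in WT and 4.42 in the array labelled KO, a log2 ratio of -1.13. Which part of the gene was deleted is not given in the sources used here, and a probe outside the deleted part checks nothing. The probe therefore does not establish the genotype of either pool, least of all at 3 weeks, and every direction below rests on the labels.

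The first comparison asks which genes differed between the arrays labelled KO and WT in the same direction at both ages. Ranked by the smaller of their 2 ratios among genes well above background on all 4 arrays, the highest genes encode the contractile and metabolic machinery of striated muscle. Acta1, skeletal muscle actin, had a log2 ratio of 8.84 at 3 weeks and 4.99 at 6 weeks. Tnnc2, fast skeletal troponin C, stood at 8.73 and 5.87, Cox6a2, the muscle form of a cytochrome c oxidase subunit, at 5.80 and 5.89, and Myh7, a slow myosin heavy chain, at 5.95 and 5.40. Tnni2, Fabp3, Pgam2, Myl3, Mybpc1, Cox8b, Cacna1s and Ak1 completed the 12 highest of this ranking, with log2 ratios between 2.87 (Ak1 at 6 weeks) and 7.24 (Tnni2 at 3 weeks). Acta1 was low but present in WT at 6 weeks, with a signal of 0.326 against 0.0237 in WT at 3 weeks, 10.9 in the array labelled KO at 3 weeks and 10.3 in that at 6 weeks. Of 50 skeletal muscle markers listed after these genes had been seen, 44 were at least 2-fold higher at both ages. The median log2 ratio of the 50 was at least 4.07 at 3 weeks and 4.11 at 6 weeks, a lower bound because 29 and 21 of them were not well above background in WT.

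Liver genes also differed at both ages. Afp, the fetal serum albumin homologue, had log2 ratios of 1.56 and 1.84, Dlk1 of 1.29 and 1.31, Spink1 of 1.15 and 1.75, and Tff3 of 2.23 and 1.14. These were the 4 of 17 fetal and neonatal liver genes at least 2-fold higher at both ages, and the list's median stood at 0.50 (percentile 100 among 10000 random lists matched on signal) at 3 weeks and 0.36 (percentile 99.8) at 6 weeks, while 1 member was at least 2-fold lower at both. With the mean of all probes per gene the list's median at 3 weeks was 0.27. Asns, asparagine synthetase and a target of the integrated stress response, was higher by 1.24 and 1.32. Des and Cryab, at 1.99 and 2.35 and at 1.71 and 2.61, were the members of the stellate cell and heat shock lists at least 2-fold higher at both ages, and both are also expressed in muscle, whose markers moved with them. Among genes at least 2-fold lower at both ages, Cyp3a44 had log2 ratios of -2.05 and -3.48, Cyp3a41b of -1.63 and -2.28, Hao2, a peroxisomal hydroxyacid oxidase, of -1.45 and -2.94, Cyp2c55 of -1.22 and -3.52 and Pnpla3, a lipid droplet lipase family member, of -1.37 and -2.10. Prom1, Tfec, Sv2c, Gngt1, Spsb4, Olfr224 and Guca1a were the others among the 12 lowest of genes well above background on all 4 arrays. The Cyp3a genes have near-identical copies, and a probe for one may also read another.

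In all, 200 genes were at least 2-fold higher at both ages and 70 at least 2-fold lower, where independent lists would share 25.06 and 15.01. Another 123 genes passed 2-fold in opposite directions, 63 higher then lower and 60 lower then higher, where independent lists would share 18.9 and 19.9, so the overlap exceeded these values in every direction. Without the 50 muscle markers, a count added after the data were seen, 156 were higher at both ages. These 156 still hold genes expressed in muscle that are not among the 50 markers, such as Ak1, Fabp3 and Cryab. Among genes whose mean signal lay above the 75th percentile, also added afterwards, 14 were higher and 6 lower. Across 18870 genes well above background on all arrays, the ratios at the 2 ages correlated with Pearson's r of 0.214 and Spearman's rho of 0.147, and 54.4% had the same sign. Genes are not independent replicates, and the correlation is across genes. limma, fitted with age and genotype on 22644 genes, has 1 residual degree of freedom and called no gene in either direction after Benjamini-Hochberg adjustment. The smallest adjusted p was 0.468. Of the 22644 genes, 1005 had an unadjusted p under 0.05 in this fit, a share below 0.05. The share was above 0.05 in 1040 of 18870 genes well above background on all 4 arrays. It was also above it with a trend in the variance prior, at 1223 of 22644. A genotype effect that differs between the ages widens the spread in this fit, so the share does not tell whether there is an effect. With a trend in the variance prior limma called 4 higher and 0 lower, the muscle genes Cox6a2, Fabp3, Myot and Sln, each at an adjusted p of 0.0446.

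**Figure D1:**
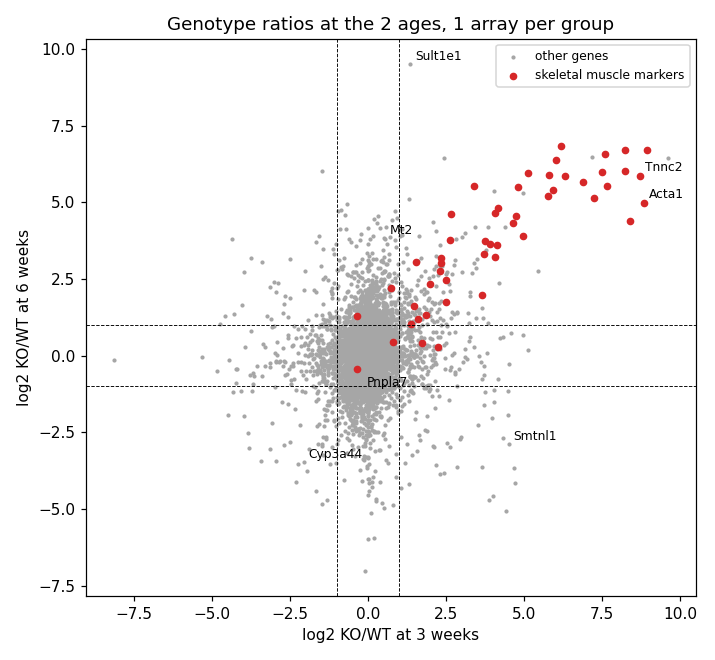
Log2 KO/WT ratio of each gene at 3 weeks (horizontal axis) against that at 6 weeks (vertical axis), 1 array per group, with dashed lines at 2-fold and ratios against an array where the gene was not well above background drawn at their bound. Skeletal muscle markers, in red, lie mostly in the upper right quadrant, with Acta1 at 8.84 and 4.99, while Sult1e1 stands at 1.36 and 9.51.

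At 3 weeks, sex-biased liver genes set the array labelled KO apart from WT. Slco1a1, an organic anion transporter higher in male liver, had a log2 ratio of 3.40, and Cyp4a12b and Cyp4a12a, male-biased fatty acid hydroxylases, had 2.07 and 1.22. Of 22 male-biased genes, 6 were at least 2-fold higher and 0 lower, with a median of 0.59 (percentile 100). Of 22 female-biased genes, 7 were at least 2-fold lower and 0 higher, with a median of -0.64 (percentile 0), among them Cyp3a44 at -2.05, A1bg at -1.66 and Hao2 at -1.45. Xist was well above background on all 4 arrays, with KO/WT log2 ratios of 0.02 at 3 weeks and 0.29 at 6 weeks, and of 4 Y-linked genes only Uty was, on the WT array at 3 weeks.

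Genes of lipid synthesis and xenobiotic defence were lower at 3 weeks. Fatty acid and triglyceride synthesis had a median log2 ratio of -0.27 (percentile 0), with 2 of 30 genes at least 2-fold lower, among them Pnpla3 at -1.37. CAR and PXR targets had a median of -0.32 (percentile 0), with 6 of 22 genes at least 2-fold lower and 1 higher. NRF2 targets and glutathione genes had a median of -0.30 (percentile 0), with Cbr3, a carbonyl reductase, at -1.75 as the 1 of 28 past 2-fold. Cholesterol synthesis and uptake, with none of 26 genes past 2-fold, had a median of -0.14 (percentile 0). Markers of neutrophils and monocytes stood at -0.40 (percentile 0), of erythroid cells at -0.19 (percentile 0.59; -0.31 with the mean of all probes), of lymphocytes at -0.17 (percentile 0.75) and of periportal hepatocytes at -0.10 (percentile 0.86, or 3.83 with lists not matched on signal). The cell cycle list, with none of 32 genes past 2-fold, had a median of -0.35 (percentile 0).

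Above the random lists at 3 weeks were also extracellular matrix genes, with a median of 0.21 (percentile 100), endothelial markers at 0.11 (percentile 99.4), pericentral hepatocyte genes at 0.10 (percentile 99.3), the unfolded protein response at 0.07 (percentile 98.4), stress response and ATF4 targets at 0.07 (percentile 98.7) and lipoprotein genes at 0.06 (percentile 98.3). Against random lists not matched on signal only the matrix genes of these 6 stood apart, with endothelial markers at percentile 97.2, pericentral genes at 96.3, the unfolded protein response at 95.1, ATF4 targets at 97.3 and lipoprotein genes at 92.7. Of genes within 1.5-fold at 6 weeks, Lmtk3, Slco1a1, Zfp521 and Stil were among the highest and Olfr1419, Hsf5, Tspoap1, Brinp2 and Olfr324 the lowest, Olfr1419 at -5.30. Each of these lowest genes was raised on the WT array at 3 weeks against all other arrays, so 1 array sets their ratios. Olfr1419 had a signal of 0.784 there, against 0.0199 in the array labelled KO. At 6 weeks its signal was 0.0188 in WT and 0.0181 in the array labelled KO. Of the highest genes, Lmtk3, Zfp521 and Stil were likewise raised on 1 array alone, that labelled KO at 3 weeks. Stil had a signal of 0.663 there against at most 0.0775 elsewhere. Altogether 624 genes were at least 2-fold higher and 629 at least 2-fold lower of 21756. Restricted to genes well above background on all 4 arrays, the counts were 233 and 179. Of the 36 lists, 8 stood above and 13 below the central 95% of random lists, where 1.8 would by chance if genes varied independently, which genes of one list need not do.

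At 6 weeks, Saa1 and Saa2, serum amyloid proteins of the acute phase, were among the genes higher in the array labelled KO and had log2 ratios of 4.44 and 4.48, Lcn2, which binds bacterial siderophores, had 3.14, and Mt2, a metallothionein, had 3.81. Sult1e1, estrogen sulfotransferase, had a signal of 15.3 against 0.0210 in WT, a log2 ratio of 9.51. Klhl3, Clec2h, Sult2a7 and Padi2, at 4.16, 3.78, 3.70 and 3.25, completed the 5 highest genes that lay within 1.5-fold at 3 weeks together with Mt2. Klhl3, Clec2h, Sult2a7 and Padi2 were raised on the array labelled KO at 6 weeks alone, with Klhl3 at a signal of 0.624 there against at most 0.0451 elsewhere. Of 26 acute phase genes, 5 were at least 2-fold higher and 0 lower, with a median of 0.39 (percentile 100).

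Cell cycle genes were lower at 6 weeks, 22 of 32 by at least 2-fold and 1 higher, with a median log2 ratio of -1.70 (percentile 0; -1.10 with normexp and quantile normalization). Mcm5, a replication helicase subunit, had -2.34 and Cdk1, the mitotic kinase, -2.06, and Top2a, not well above background in the array labelled KO, had a log2 ratio of -2.70 or below. Interferon-stimulated genes had a median of -0.67 (percentile 0), with 7 of 28 at least 2-fold lower, among them Cxcl10 at -1.30 and Bst2 at -1.10. Macrophage markers stood at -0.75 (percentile 0), with Folr2 at -1.32, endothelial markers at -0.43 (percentile 0), stellate cell markers at -0.39 (percentile 0.03) and matrix genes at -0.39 (percentile 0), and moved with them. Heat shock genes had a median of -0.70 (percentile 0), with Hsp90aa1 at -1.37, and p53 targets one of -0.42 (percentile 0). Of genes within 1.5-fold at 3 weeks, Nkd2, Fjx1, Fthl17a, Cnr2, the cannabinoid receptor 2, and Vmn2r121 were lowest, from -4.74 for Nkd2 to -3.59 for Vmn2r121. Of these, Fjx1, Fthl17a and Vmn2r121 were raised on the WT array at 6 weeks alone, with Fjx1 at a signal of 0.418 there against at most 0.0244 elsewhere.

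Metabolic lists moved both ways at 6 weeks. Gluconeogenesis and glycogen genes had a median of 0.52 (percentile 100), with 4 of 24 at least 2-fold higher and 1 lower, and Ppargc1a, a coactivator of the fasting response, at 1.25. Urea cycle and amino acid catabolism stood at 0.39 (percentile 100; 0.18 with quantile normalization), cholesterol synthesis at 0.35 (percentile 100), bile acid genes at 0.23 (percentile 98.0) and pericentral genes at 0.43 (percentile 100). Fatty acid and triglyceride synthesis stood at -0.46 (percentile 0), with 5 of 30 at least 2-fold lower, among them Pnpla3 at -2.10 and malic enzyme, Me1, at -1.21. NRF2 and glutathione genes stood at -0.42 (percentile 0), with 6 of 28 at least 2-fold lower, and PPAR-alpha targets at -0.20 (percentile 0; -0.06 with the mean of all probes). Core clock and output genes had a median of 0.87 (percentile 100), with 8 of 21 at least 2-fold higher and 3 lower. The time of day at which the livers were taken is not given in the sources used here, and clock genes vary with it. A difference in time between the pools cannot be told apart from genotype, for clock genes or for any other gene that varies with it. Dbp, a clock output, had 1.18 and Arntl, which drives the clock, -1.23. Female-biased genes stood at -0.14 (percentile 0.48, or 2.90 with lists not matched on signal), with 4 of 22 at least 2-fold higher and 5 lower, and male-biased genes at 0.23 (percentile 97.4), with 5 of 22 higher and 2 lower. Cyp4a12b had 2.59 and Cyp3a44 -3.48.

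Lists that stayed within the central 95% of random lists matched on signal at both ages included hepatocyte markers, at -0.04 and 0.21, the respiratory chain, at -0.02 and 0.18, cholangiocyte markers, at -0.09 and -0.28, and pancreatic and adipose markers, at -0.05 and 0.35. With quantile normalization the 6-week medians of hepatocyte markers and the respiratory chain were 0.06 and 0.01, with the mean of all probes that of cholangiocyte markers was -0.04, and with no filter the 3-week median of pancreatic and adipose markers was -0.33. With random lists not matched on signal, cholangiocyte markers stood at percentile 1.65 and pancreatic and adipose markers at 99.2 at 6 weeks, both outside the central 95%. In all, 1388 genes were at least 2-fold higher and 969 lower of 21384 at 6 weeks, and 699 and 572 of those well above background on all 4 arrays. On the KO array at 6 weeks 1 of 10 quality metrics was out of range, a spike-in spot variation of 11.1%, and the median variation between spots of one probe was 7.31% against 4.72% on the WT array. Of the 36 lists, 8 stood above and 12 below the random lists.

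**Figure D2:**
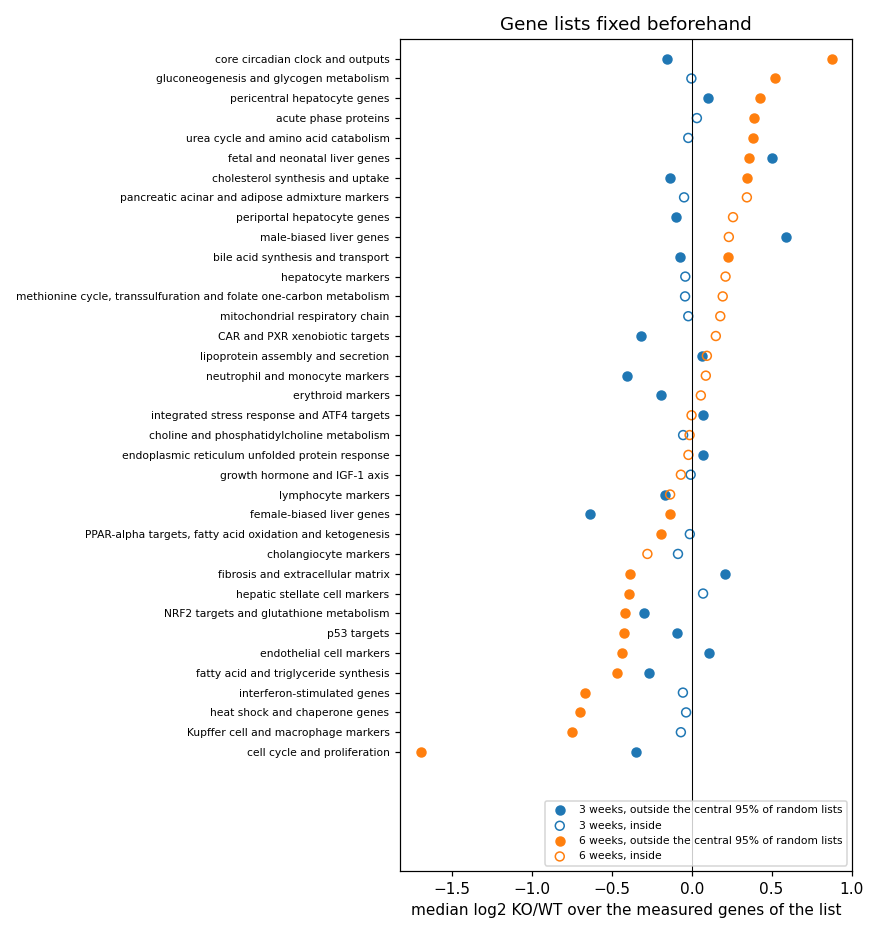
Median log2 KO/WT ratio of each of the 36 gene lists (horizontal axis) at 3 weeks (blue) and 6 weeks (orange), 1 array per group, filled where the median lay outside the central 95% of 10000 random lists matched on signal. Cell cycle genes lie lowest at 6 weeks, at -1.70, and clock genes highest, at 0.87.

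Choline, phosphatidylcholine and methionine genes, the subject of the series, differed little at 3 weeks. Of 31 choline and phosphatidylcholine genes, Gdpd3, at 1.27, was at least 2-fold higher and Lpcat1, at -2.56, lower, with a median of -0.05 (percentile 2.79). Lpcat1 had a signal of 0.218 in WT at 3 weeks, against 0.0369 in the array labelled KO. Its signals at 6 weeks were 0.0265 in WT and 0.0426 in the array labelled KO, so only the WT array at 3 weeks stood out. At 6 weeks Gpcpd1, which cleaves glycerophosphocholine, was 2.68 higher on the log2 scale, with a signal of 2.91 against 0.453 in WT, after 0.69 at 3 weeks. Chka, choline kinase alpha, had -1.43 and Pnpla7 itself -1.13, and the list's median was -0.01 (percentile 12.3). Pemt, which methylates phosphatidylethanolamine, stood at -0.12 and -0.09, Pcyt1a at -0.17 and 0.23, and Pnpla8 and Pnpla6, relatives of Pnpla7, at 0.10 and 0.43 and at -0.04 and -0.01.

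None of 39 methionine, transsulfuration and folate genes passed 2-fold at 3 weeks. At 6 weeks 4 did upward: Bhmt, which remethylates homocysteine with betaine, at 1.78, Nnmt, which methylates nicotinamide, at 1.40, Ahcy, which hydrolyses S-adenosylhomocysteine, at 1.14, and Mat1a, which makes S-adenosylmethionine in hepatocytes, at 1.07. Csad, on the route from cysteine to taurine, had -2.90 and Gclc, of glutathione synthesis, -1.18. Gnmt stood at 0.78, Cth at 0.88, Cbs at -0.46 and Mtr at -0.07. The list's median was -0.04 (percentile 4.80) at 3 weeks and 0.19 (percentile 96.8) at 6 weeks, inside the central 95% at both ages, but at percentile 97.9 at 6 weeks, outside it, with random lists not matched on signal.

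In the growth hormone and IGF-1 list Igfbp1, an IGF-binding protein, stood at 0.93 and 1.20, Egfr at 1.12 and 0.09, and Fgf21, a fasting-induced hormone, at -0.19 and -1.96. Igf1 itself stood at -0.20 and -0.18. The list's medians of -0.01 (percentile 36.3) and -0.07 (percentile 5.30) lay among the random lists.

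**Figure D3:**
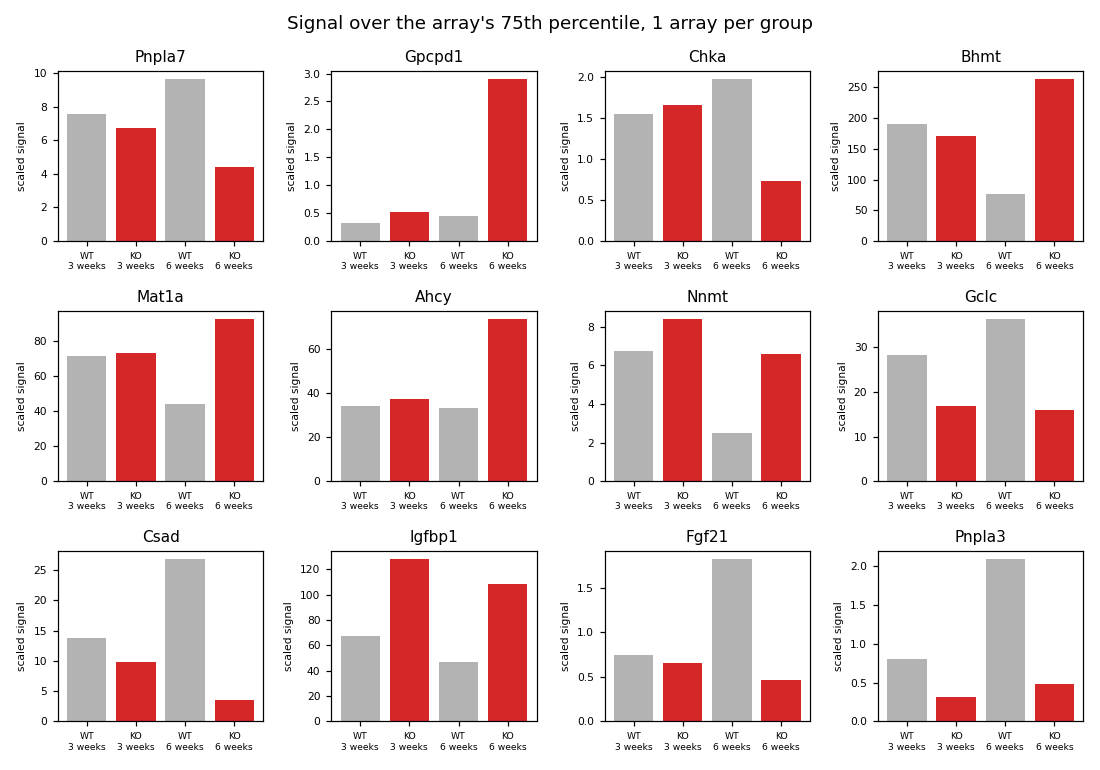
Signal of 12 genes in units of the array's 75th percentile (vertical axes, linear, from 0) on the WT (grey) and KO (red) arrays at each age, each bar 1 array of 5 pooled livers with no error bar. Bhmt reached 264 in the array labelled KO at 6 weeks against 76.6 in WT, and Pnpla7 4.42 against 9.65.

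From 3 to 6 weeks in WT, genes of the newborn liver, blood formation and growth were lower. H19, an imprinted RNA of fetal liver, had a 6-over-3-week log2 ratio of -6.45, Tff3 of -4.90, Tceal5 of -4.83 and Akr1c18 of -4.59. Slc4a1, the red cell anion exchanger, had -4.56. The medians of fetal and neonatal genes (-1.78), erythroid markers (-1.75), neutrophil and monocyte markers (-2.14), cell cycle genes (-1.58), matrix genes (-0.87) and cholesterol synthesis (-0.77) all stood at percentile 0. Tiam2, Smtnl1, Dmbt1, Fjx1, Serpina4-ps1, Reg3g, Vmn2r121 and Acta1 had the largest upward ratios, from 4.79 for Tiam2 to 3.78 for Acta1, while the 29 muscle markers with a ratio there went both ways, 19 above 0 and 10 at or below it, with a median of 0.42 and Cox8b at -2.88. Choline and phosphatidylcholine genes stood at 0.27 (percentile 100) and interferon-stimulated genes at 0.41 (percentile 100). In all 772 genes were at least 2-fold higher and 1239 lower at 6 weeks, with 420 and 608 among those well above background on all arrays.

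In the arrays labelled KO, cell cycle genes had a 6-over-3-week median of -2.81, fetal and neonatal genes of -1.85, matrix genes of -1.53 and erythroid markers of -1.18, all at percentile 0. CAR and PXR targets stood at 0.60 (percentile 100), methionine genes at 0.28 (percentile 99.3) and clock genes at 0.42 (percentile 100), against -0.70 (percentile 0) for clock genes in WT. Here 1322 genes were at least 2-fold higher and 1376 lower, with 723 and 846 among those well above background on all arrays.

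The last comparison sets the KO/WT ratio at 6 weeks against that at 3 weeks. Sult1e1 had the largest upward difference, 8.15 on the log2 scale, followed by Myo7b at 5.68 and Col4a3 at 5.49, and Olfr1419 and Cdkl1 completed the 5. For Olfr1419 and Cdkl1 the WT array at 3 weeks alone stood out. Their signals there were 0.784 and 0.290, against at most 0.0199 and 0.0571 elsewhere. For Myo7b and Col4a3 the array labelled KO at 6 weeks alone stood out, with signals of 0.521 and 0.345 against at most 0.0598 and 0.0474 elsewhere. Smtnl1, at -7.39, Serpina4-ps1, at -5.67, and Pgk2, also at -5.67, had the largest downward ones, with Otulinl and Nkd2 after them. Of 18870 genes, 158 had a ratio at least 4-fold higher at 6 than at 3 weeks and 129 one at least 4-fold lower, and no test of these differences can be had from 4 arrays.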

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

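Among the tests below, those of muscle markers near background in WT and of more males in the KO pools were chosen only after the values had been seen, and the interval applied to second probes was added afterwards. The differences between ages in the next 2 paragraphs were not tested, since each age has 1 array per genotype.

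Named genes at least 2-fold different in opposite directions at the 2 ages stand out first. The KO/WT log2 ratio went from 4.51 at 3 weeks to -2.88 at 6 weeks for Smtnl1, a difference of -7.39. For Pgk2 it went from 2.97 to -2.70, a difference of -5.67, and for Otulinl from 2.12 to -2.99, a difference of -5.11. It went from -1.57 to 3.92 for Col4a3, a difference of 5.49, and from -3.22 to 1.29 for Cdkl1, a difference of 4.51.

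Gene lists whose medians stood apart in opposite directions were clock genes, from -0.16 at 3 weeks to 0.87 at 6 weeks, a difference of 1.03, and cholesterol synthesis, from -0.14 to 0.35, a difference of 0.48. Bile acid genes went from -0.07 to 0.23, a difference of 0.30. Matrix genes went from 0.21 to -0.39, a difference of -0.60, and endothelial markers from 0.11 to -0.43, a difference of -0.54. With random lists not matched on signal, bile acid genes at percentile 4.24 and endothelial markers at 97.2 no longer stood apart at 3 weeks.

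Striated muscle genes led the genes higher at both ages when ranked by the smaller of their 2 ratios, and pieces of skeletal muscle taken with the liver may be the source. The test set beforehand asked for at least 90% of the muscle markers outside the 12 named genes to be 2-fold higher at both ages, and 34 of 40, or 85.0%, were, which misses that bound and also lies above the 50% that would have argued against it. The 6 that missed were Car3, Pvalb, Tnnc1, Tnnt1, Tpm2 and Xirp1. Car3, Pvalb, Tnnt1 and Tpm2 had WT signals of 49.1, 0.320, 0.728 and 0.634 at 3 weeks, and a given amount of muscle RNA raises such a ratio less. Tnnc1 and Xirp1 had lower ones, 0.148 and 0.0410. Of all 50 markers, 29 were not well above background in WT at 3 weeks and 21 at 6 weeks. Acta1, an abundant one, reached signals of 10.9 and 10.3 in the arrays labelled KO. Among the 31 markers under 0.1 of the 75th percentile in both WT arrays, a restriction chosen after the values were seen, 30 or 96.8% were, which goes with muscle tissue but cannot count as an independent test. Brown fat is argued against: the median log2 ratio of 7 of its markers not expressed in muscle was 0.37 at 3 weeks and 0.20 at 6 weeks, with Ucp1 at -2.66 and -0.21, and muscle genes switched on in KO liver cells stay open and untested.

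Sex-biased genes differed at 3 weeks, with male-biased genes higher and female-biased genes lower in the array labelled KO. A mix with more males in the KO pools may give this, and would lower Xist and bring Y-linked transcripts there. Neither was seen: Xist had signals of 1.27 in WT and 1.29 in the array labelled KO at 3 weeks, a log2 ratio of 0.0204. None of the 8 values of Y-linked genes on the arrays labelled KO was well above background. Across all 4 arrays Xist was well above background, and 1 of 16 Y-linked values was, Uty on the WT array at 3 weeks. By these genes the KO pools read as female, which argues against more males in them. But no array here is known to hold males, so how well the Y-linked probes read male liver was not checked. The spread between pools is also unknown. The test set beforehand asked for more females, with Xist 2-fold higher, where it was 0.29 higher at 6 weeks, and that direction is not the one the pattern needs. An effect of genotype stays open and untested.

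Opposite directions at the 2 ages were seen for 123 genes, 96 of them not well above background on every array, with a median log2 signal of -5.22 against -1.04 for all genes. Errors of single spots may be the source, but none of 269 genes read by 10 spots was among them, 0% with an exact 95% upper limit of 1.36%, while 0.385% would be at the rate of other genes of like signal, so the count is too small to decide. Errors of one probe stay open too: 0 of 3 second probes, or 0%, moved the same way, with an exact upper limit of 70.8%.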

How the results depend on the processing

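Counts in this order are given for each setting: KO over WT at 3 weeks higher and lower, at 6 weeks higher and lower, 6 over 3 weeks in WT higher and lower, in KO higher and lower, both ages higher, lower and opposite, and the difference between ages higher and lower at 6 weeks. At a 1.5-fold threshold they were 1101, 1192, 2660, 2227, 1736, 2276, 2927, 2862, 376, 259, 340, 553 and 468. At a 3-fold threshold they were 373, 310, 609, 410, 349, 587, 583, 674, 101, 20, 46, 37 and 36. With no filter on dim genes they were 1304, 1212, 2196, 1641, 1345, 1996, 2026, 2237, 393, 218, 436, 1188 and 858. With normexp and quantile normalization they were 311, 216, 549, 497, 382, 494, 588, 717, 88, 23, 29, 50 and 56. With only genes well above background on all 4 arrays, the counts up to the opposite directions were 233, 179, 699, 572, 420, 608, 723, 846, 77, 27 and 27. With a mean signal above the 75th percentile, a setting added after seeing the data, the counts of KO over WT and of differences were 30, 25, 207, 137, 14, 6, 2, 16 and 19. Thresholds and filters change the counts by construction, since they change which genes pass; the cause was not tested for normexp. limma with a trend in its variance prior called 4 genes higher, Cox6a2, Fabp3, Myot and Sln, against 0 otherwise, and its smallest adjusted p ranged from 0.0446 with the trend to 0.545 with quantile normalization. All counts stayed within 1.5 times under quantile normalization, median scaling, the mean of probes, outlier spots kept and the authors' value table, as did all 9 without the muscle markers, also added after seeing the data. No named gene past 2-fold and no list standing apart changed sign under any scaling or filter, and 12 of 72 list percentiles crossed the limits with random lists not matched on signal. Sizes did change: of 610 ratios of named genes and medians of lists, 137 moved with normexp and quantile normalization and 51 with the mean of all probes. A ratio counted as moved beyond the interval from spot variation, and a list median beyond its standard error over genes. Genes not well above background on an array have only a bound there.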

Other observations

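The tests below were set before their results were seen, but the interval on the share near Pnpla7 and the weight given to simulated noise in the maturation test were added afterwards.

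Clock genes at 6 weeks, chosen for naming after their values were seen, included Ciart, with a KO/WT log2 ratio of 2.97, Usp2 at 2.07, Per3 at 1.94 and Per1 at 1.35, while Nfil3 stood at -1.30. In the same comparison Mt1, a metallothionein like Mt2, stood at 2.70 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.55. At 3 weeks Mup20 and Mup1, major urinary proteins of male liver, stood at 2.13 and 2.07.

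Of other tissues, 9 cardiac-restricted markers had medians of 0.10 and 0.40, with Myh6 at -0.06 and 0.34 and Nppa at 0.17 and 0.40. Of these 9, 2 were at least 2-fold higher at 3 weeks and 3 at 6 weeks, with Actc1 and Sln, which is also on the skeletal muscle list, higher at both, while Nppb stood at -3.31 at 6 weeks. The 16 brown adipose markers measured had medians of 0.19 and 0.33, with 3 at least 2-fold higher at each age and 2, Cox8b and Fabp3, at both, and some of them are expressed in muscle.

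A hypothesis was that genes flanking Pnpla7, carried along from the embryonic stem cell strain, make up much of the genes 2-fold different at both ages. Of 267 such genes with a position, 4 lay within 20 Mb of the Pnpla7 probe, 1.5% with an exact 95% interval from 0.410% to 3.79%, against 1.88% of all measured genes, which is far below the 10% the hypothesis asked for.

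A further hypothesis was that the KO liver matures late, which would make KO/WT ratios run against the change from 3 to 6 weeks. Across 18870 genes, r was 0.227 between the KO/WT ratio at 3 weeks and the change in WT, and 0.558 between that at 6 weeks and the change in KO. Each pair shares an array, and noise alone gave 0.498 and 0.499 in a simulation, with covariances of 0.0141 and 0.0141 against 0.0470 and 0.208 observed. The simulation gave every array equal noise, which fixes its r in advance, and took the size of that noise from the 3-week ratios alone. The KO/WT ratios at 6 weeks spread more widely, with a robust SD of 0.339 against 0.168, so the observed 0.208 has no simulated value of matched noise. The bound set beforehand, both above 0, is what a shared array gives with no effect, so delayed maturation was neither supported nor excluded.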
